A study of Homo sapiens with 8 samples.

How the data were processed

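Total RNA from human ovarian carcinoma cell lines was measured on Affymetrix Human Gene 1.0 ST arrays, which carry 1 biotin-labelled sample each. Each of the 8 arrays gave 1 column of values, and 33297 probe sets were listed. The deposited values lay between 1.8 and 14.99 with near-equal medians and quartiles on every array, the range of log2 intensities. The log2 scale of the deposited values was read from that range, since the log base is not given in the sources used here. Partek is named in the submitters' processing notes, with no version and no role. The background correction, the normalization between arrays and the summary of probes into probe sets are not given in the sources used here. The values were rounded to 2 decimals, so differences of about 0.01 cannot be resolved. The medians of the 2 arrays were 6.71 and 6.70 for untreated A2780, 6.72 and 6.68 for A2780CP20, 6.70 and 6.70 at 24 h, and 6.66 and 6.67 at 48 h.

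Groups and replicate numbers were taken from the sample titles. There were 4 groups of 2 arrays: untreated A2780, untreated A2780CP20, A2780 with temsirolimus for 24 h, and A2780 with temsirolimus for 48 h. Nothing in the labels says that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. The precision is limited by the number of arrays.

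Probe sets were named through the platform's annotation table, in which 19460 had 1 gene symbol, 1754 had several and 12083 were unnamed here. Only probe sets with 1 symbol were used. Where a gene had more than 1 probe set (769 genes), the one with the highest mean over the 8 arrays stood for it, which left 18417 genes. Of these, 18389 were matched by gene number to a RefSeq gene table of assembly GRCh38.p14 and 28 were not. That table was used only for the type of gene, the chromosome and the order of neighbouring genes, and none of its coordinates are printed because the build behind the array annotation is not given in the sources used here.

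The main test was limma version 3.58.1 in R version 4.3.3. A linear model with 1 coefficient per group was fitted to all 8 arrays, followed by empirical Bayes moderation (residual degrees of freedom 4, prior degrees of freedom 4.48), two-sided tests and Benjamini-Hochberg adjustment over the 18417 genes. A gene was called when its adjusted p was under 0.05. The comparisons were A2780CP20 versus A2780, temsirolimus at 24 h and at 48 h versus untreated A2780, and 48 h versus 24 h. Standard errors are those of the moderated fit.

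Before the data were examined, 32 gene lists were fixed: 28 of pathways and cell states and 4 of markers of other cell types. They were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the 32 lists. Camera with an estimated correlation and limma's fry were alternatives. Fry tests whether the genes of a list move on balance in 1 direction and does not compare the list with other genes.

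The genes named were also set by a rule fixed beforehand. For each comparison with untreated A2780 the rule took the 10 higher and 10 lower called genes with the largest change and no overlap between the groups' arrays, or all of them where fewer passed. For 48 h versus 24 h it took 5 and 5. From each gene list it took up to 4 called members, or up to 2 with the smallest p where none was called. A fixed set of genes of mTOR signalling, growth control and platinum handling was always included. Small RNAs, unnamed loci and Y-linked genes were left out. Genes with near-identical copies or many processed pseudogenes are named as uncertain. Not all genes taken by the rule are named.

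Comparisons that share the 2 untreated A2780 arrays have correlated errors, so correlations and shared calls were set beside 100 simulated draws of unchanged groups that share those arrays. For shared calls the draws gave the overlap of calls and that of lists as long as the observed ones, taken by smallest p, and the overlap of independent lists was also given. The gene test was tested on simulated data with known changes on the same 18417 genes. It recovered 85.1% of genes changed by 1 on the log2 scale for A2780CP20 versus A2780, 83.6% for 24 h, 73.1% for 48 h and 74.6% for 48 h versus 24 h. At a log2 change of 0.5 the shares were 29.9%, 19.4%, 28.4% and 19.4%. Between 2 and 7 unchanged genes were called. Each of these shares rests on 67 changed genes, so their differences between comparisons may be sampling error. In the simulated data 18198 to 18204 of the genes were unchanged. The unadjusted p needed for a call depends on how many genes change. The shares therefore do not give the power of the real comparisons, where 3388, 5551, 33 and 5702 genes were called.

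Alternatives were quantile normalization, centring each array on its median, leaving out the dimmest 25% of genes, the mean of the probe sets of a gene, leaving out each array in turn, a replicate block, fits of only the groups compared, a prior with an intensity trend, a robust prior and a test of every probe set. A pseudocount was not used because the values were already on a log scale. Fits without both arrays labelled temsirolimus 24 h were added after the data were seen. Figures were drawn with matplotlib version 3.10.9.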

Results

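Gene expression was measured in A2780, a human ovarian carcinoma cell line, in its subline A2780CP20, and in A2780 cells given temsirolimus for 24 h or 48 h. Temsirolimus is a rapamycin ester that inhibits the kinase complex mTORC1. Cells were grown in RPMI medium with serum, and the drug stock was in DMSO. The label of the control arrays gives no treatment and does not state whether vehicle was added. There were 2 arrays in each of the 4 groups, and array medians lay between 6.66 and 6.72 log2 units. Changes below are log2 differences of group means ± the standard error of the limma fit (n = 2 arrays per group), with adjusted p from limma.

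The arrays labelled temsirolimus 24 h stood apart from the other 6 arrays. Across genes, the 2 arrays of each group correlated at r = 0.996 for untreated A2780, 0.991 for A2780CP20, 0.997 at 24 h and 0.997 at 48 h. The arrays labelled 24 h correlated with every other array at 0.950 to 0.952, whereas the arrays labelled 48 h correlated with untreated A2780 at 0.994 to 0.996. Genes are not independent replicates, so these values describe the arrays and carry no test. The first principal component held 70.2% of the variance and placed the arrays labelled 24 h at 63.5 and 63.8, with all others between -24.0 and -14.2.

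**Figure D1:**
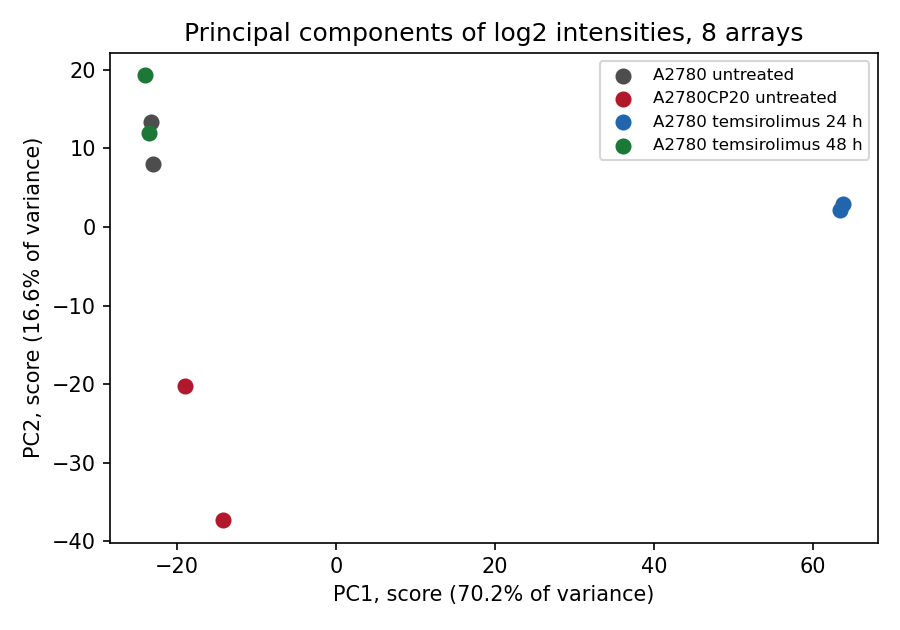
Scores of the 8 arrays on the first and second principal components of log2 intensities, 1 point per array, coloured by group. The arrays labelled 24 h lie at 63.5 and 63.8 on the first component, and the A2780CP20 arrays lie at -37.3 and -20.3 on the second.

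The comparison of A2780CP20 with A2780 asks how expression differs between the subline and its parent line, both untreated. Changes are given under the labels of the arrays, and an exchange of labels with the arrays labelled 24 h was not excluded. The largest fall was in TXNIP, which encodes a thioredoxin-binding protein that restrains glucose uptake, at -2.56 ± 0.12 (5.88-fold lower, adjusted p = 0.000274). The largest rise was in ID2, an inhibitor of basic helix-loop-helix transcription factors, at 1.23 ± 0.09 (2.34-fold higher, adjusted p = 0.000915). Its relative ID1 rose by 0.97 ± 0.09. SLC7A5, the large neutral amino acid transporter, rose by 1.13 ± 0.09. In all, 3388 of 18417 genes were called, 1174 higher and 2214 lower, and 125 of them changed at least 2-fold, 6 up and 119 down.

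Other genes among the largest rises were IFI30, a lysosomal thiol reductase (1.05 ± 0.10), HMGA1, a chromatin protein whose probes are uncertain because of processed pseudogenes (1.01 ± 0.14), CCDC86 (1.00 ± 0.11), DNAAF5 (0.97 ± 0.09), the kinase gene MAP2K3 (0.97 ± 0.10), HCFC1 (0.97 ± 0.14) and NABP2 (0.92 ± 0.10). The largest falls after TXNIP were in SMIM14 (-1.96 ± 0.14), TCP11L2 (-1.93 ± 0.15), the transcriptional repressor gene HBP1 (-1.85 ± 0.15), SLC44A5 (-1.75 ± 0.12), KLHL24 (-1.56 ± 0.10), the iron reductase gene CYBRD1 (-1.55 ± 0.11), the ligand gene BMP5 (-1.52 ± 0.14), the noncoding EOLA1-DT (-1.52 ± 0.22) and DNAJB4 (-1.46).

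Of the 32 gene lists, 3 were shifted. In cholesterol synthesis and uptake, 8 of 19 measured genes fell and none rose (9 lower adjusted over the list alone, camera adjusted p = 0.0101). MSMO1 (-1.31 ± 0.10) and SC5D (-0.99 ± 0.15), which encode sterol-modifying enzymes, and HMGCS1 (-0.72 ± 0.10), which encodes an early enzyme of the mevalonate pathway, were among them. Of the 31 targets of ATF4 and amino acid genes, 10 rose and 1 fell (12 and 2 adjusted over the list alone, camera adjusted p = 0.0207), including the glutamine transporter gene SLC1A5 (0.86 ± 0.11), ATF5 (0.75 ± 0.11) and TRIB3 (0.49 ± 0.12). In DNA repair, 7 of 25 genes fell and none rose (9 adjusted over the list alone, camera adjusted p = 0.0207), with PMS1 at -0.84 ± 0.14, ERCC4 at -0.70 ± 0.10 and REV1 at -0.62 ± 0.10. None of these lists was called with an estimated correlation (adjusted p = 0.427 for each). The DNA repair call ended with quantile normalization (adjusted p = 0.089), without the dimmest genes (0.0877), without A2780 untreated replicate 2 (0.101) and without A2780CP20 untreated replicate 1 (0.0973). The cholesterol and ATF4 calls ended without A2780CP20 untreated replicate 2 (adjusted p = 0.108 for each).

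Lists without a camera call still held called genes. Of all genes tested, 18.4% were called in this comparison, so called members alone do not mark a list. Interferon-stimulated genes gave 6 lower and none higher of 26 (9 lower and 2 higher adjusted over the list alone, camera adjusted p = 0.237, adjusted p = 0.462 with an estimated correlation), including IFI6 (-1.14 ± 0.11) and IFIT1 (-1.03 ± 0.08). Mesenchymal genes gave 7 lower and 1 higher of 26 (8 and 1 adjusted over the list alone, camera adjusted p = 0.237, adjusted p = 0.462 with an estimated correlation), including POSTN (-1.07 ± 0.14) and ACTA2 (-0.95 ± 0.09). Of 25 mTOR and PI3K-AKT components, 6 rose and 4 fell (7 and 5 adjusted over the list alone, camera adjusted p = 0.922, adjusted p = 0.961 with an estimated correlation). EIF4EBP1, a repressor of translation that mTORC1 phosphorylates, rose by 0.62 ± 0.12. PDCD4, another repressor of translation, was at -0.95 ± 0.10, RICTOR, a subunit of mTORC2, at -0.67 ± 0.15 and PIK3R1 at -0.65 ± 0.11. MTOR itself measured 0.02 ± 0.10. Of 17 platinum and drug transport genes, 2 fell and 1 rose (2 lower and none higher adjusted over the list alone, camera adjusted p = 0.237, adjusted p = 0.525 with an estimated correlation). SLC47A1 was at -0.49 ± 0.09, ABCC5 at -0.45 and ABCC1 at 0.40 ± 0.12, while the copper transporter genes ATP7A (-0.55 ± 0.18, adjusted p = 0.064), ATP7B (-0.17 ± 0.14) and SLC31A1 (-0.22 ± 0.12) did not pass, nor did GSTP1 (0.01 ± 0.10), ERCC1 (-0.24 ± 0.10) or ABCC2 (0.02 ± 0.10).

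The count of 3388 depended on the arrays in the fit: it was 1022 with only the 2 groups compared, 1206 without A2780 untreated replicate 1, 974 without A2780 untreated replicate 2 and 5543 without A2780CP20 untreated replicate 2. The 2 A2780CP20 arrays also differed more from each other (SD of log2 differences 0.287) than those of untreated A2780 (0.181). The fit shares 1 estimate of the spread per gene over all groups, so standard errors and adjusted p for A2780CP20 can be too small.

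The comparison at 24 h asks how A2780 responded to a day of temsirolimus. On the arrays labelled 24 h, the largest changes exceeded 100-fold in both directions. MUC15, a membrane mucin gene, was higher by 7.30 ± 0.09, the tight junction gene CLDN1 by 7.04 ± 0.14 and ATP1B1, a subunit of the sodium pump, by 6.98 ± 0.11. DKK1, a secreted WNT antagonist, was lower at -7.59 ± 0.14, and VCAN, a matrix proteoglycan, at -6.41 ± 0.11. In all, 5551 genes were called, 2738 higher and 2813 lower, of which 1180 changed at least 2-fold, 170 at least 8-fold and 31 at least 32-fold. In the dimmer group MUC15, MID1, EYA4, P3H2, DKK1, OSTN, GPRIN3, NDST4 and ABCB1 lay below 5.03, the lowest lower quartile of any array, where signal over background is not known. Their changes are given as measured and can be understated, and their order is not certain.

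Further large rises were in MID1 (6.93 ± 0.13), EYA4 (5.90 ± 0.15), P3H2 (5.88 ± 0.13), the homeobox gene ISL1 (5.71 ± 0.12), CLDN16 (5.69 ± 0.12), VGLL3 (5.68 ± 0.09) and ANKRD1 (5.68 ± 0.11). Further large falls were in OSTN (-7.21 ± 0.17), the cytochrome P450 gene CYP1B1 (-6.11 ± 0.09), HAPLN1 (-6.05 ± 0.17), SNAI2, a repressor of epithelial genes (-5.98 ± 0.16), GPRIN3 (-5.96 ± 0.19), NDST4 (-5.55 ± 0.18), CBLN2 (-5.51 ± 0.10) and LUM (-5.40 ± 0.17). The drug efflux pump gene ABCB1 rose by 3.31 ± 0.12, the aldehyde dehydrogenase gene ALDH1A1 by 2.96 ± 0.14 and EPCAM by 2.17 ± 0.11. LIN28A, an RNA-binding protein gene of stem cells, changed by -3.37 ± 0.10. KRT18 measured 2.94 ± 0.21 and is uncertain because of its many pseudogenes. The lists that hold these genes were not called. Drug transport genes had 2 higher and 6 lower of 17 (camera adjusted p = 0.192). Pluripotency genes had 1 higher and 5 lower of 17 (camera adjusted p = 0.0631). Epithelial and Mullerian genes had 2 higher and 1 lower of 23 (camera adjusted p = 0.996).

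Genes of growth control also changed on these arrays. MYC fell by 1.42 on the log2 scale and CCND1, which encodes cyclin D1, by 0.80. JUN rose by 2.09 ± 0.10, and CDKN1A fell by 0.50. ATP7B and ATP7A fell by 1.21 and 0.61 on the log2 scale. MTOR (-0.18 ± 0.10), RPS6KB1 (-0.22 ± 0.11), EIF4EBP1 (0.18 ± 0.12), FKBP1A, which encodes the protein that temsirolimus binds (0.16 ± 0.11), SLC31A1 (0.12 ± 0.12), ABCC2 (-0.02 ± 0.10), GSTP1 (0.04 ± 0.10) and ERCC1 (-0.07 ± 0.10) were not called.

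At 24 h, 8 of 32 lists were shifted. Mesenchymal genes had 15 lower and 3 higher of 26 (the same counts adjusted over the list alone, camera adjusted p = 0.000198, adjusted p = 0.231 with an estimated correlation), among them COL1A2 (-5.39 ± 0.11) and DCN (-3.79 ± 0.08). Of 25 ribosome biogenesis genes, 14 rose and 1 fell (18 and 2 adjusted over the list alone, camera adjusted p = 0.000493, adjusted p = 0.285 with an estimated correlation), with LYAR at 1.21 ± 0.11, RRP9 at 1.19 ± 0.14 and RRP12 at 1.01 ± 0.09. MYC, the member that fell, activates many of the others. Targets of ATF4 and amino acid genes had 14 higher and 2 lower of 31 (17 and 2 adjusted over the list alone, camera adjusted p = 0.00171, adjusted p = 0.246 with an estimated correlation), led by the cystine transporter gene SLC7A11 (2.43 ± 0.13), TRIB3 (0.82 ± 0.12) and DDIT3 (0.75 ± 0.09), while SESN2 was at -0.70 ± 0.11.

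Cytosolic ribosomal protein genes had 8 lower and none higher of 24 (9 adjusted over the list alone, camera adjusted p = 0.0152, adjusted p = 0.251 with an estimated correlation), with RPL22 at -1.54 ± 0.10 and RPL13 at -0.72 ± 0.09, both uncertain because of pseudogenes. DNA replication genes had 9 higher and 1 lower of 33 (9 and 2 adjusted over the list alone, camera adjusted p = 0.0184, adjusted p = 0.270 with an estimated correlation), including RRM2 (0.85 ± 0.11) and MCM10 (0.53 ± 0.09). Mitotic genes had 14 higher and 4 lower of 29 (15 and 4 adjusted over the list alone, camera adjusted p = 0.0152, adjusted p = 0.585 with an estimated correlation), with KIF2C at 0.83 ± 0.10, PLK1 at 0.73 ± 0.13 and CENPF at -1.08 ± 0.10. G1 cyclins and CDK inhibitors had 7 lower and 2 higher of 15 (the same counts adjusted over the list alone, camera adjusted p = 0.0384, adjusted p = 0.270 with an estimated correlation). CCNG2 (-1.86 ± 0.11), CDK6 (-1.85 ± 0.15) and the inhibitor gene CDKN1B (-1.15 ± 0.09) fell. Targets of p53 had 12 lower and 3 higher of 20 (13 and 3 adjusted over the list alone, camera adjusted p = 0.0154, adjusted p = 0.251 with an estimated correlation), with TP53INP1 at -1.74 ± 0.19, TP53I3 at -1.43 ± 0.10 and ZMAT3 at 1.52 ± 0.09. The call of G1 cyclins and CDK inhibitors ended with quantile normalization (adjusted p = 0.0704), without the dimmest genes (0.0838), without A2780 untreated replicate 1 (0.0502) and without A2780 temsirolimus 24 h replicate 1 (0.0522), and that of ribosomal proteins ended without A2780 untreated replicate 2 (0.0543).

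A whole chromosome was also shifted on the arrays labelled 24 h. The 157 expressed genes of chromosome 13 had a median change 0.44 log2 below that of all expressed genes there (departure -0.44), and 72.6% of them were lower. The next largest departure of any chromosome was 0.13, and between arrays of the same group none passed 0.09. On the A2780CP20 arrays chromosome 13 lay at -0.195 and chromosome 19 at 0.195. The count of 5551 was 3621 without A2780 temsirolimus 24 h replicate 1.

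**Figure D2:**
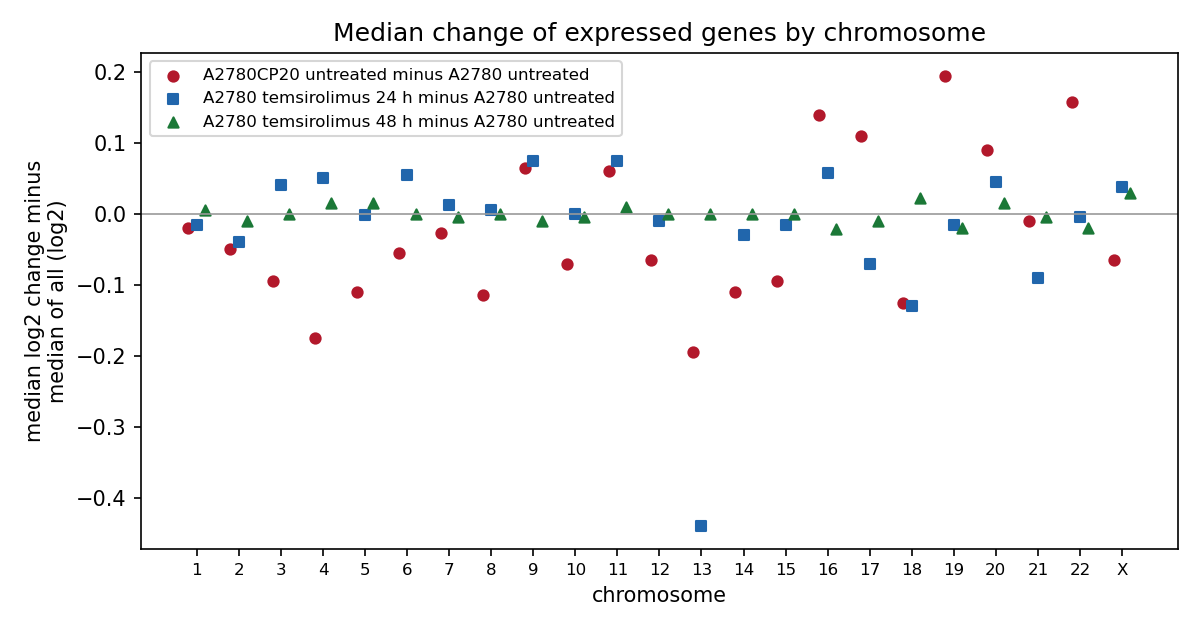
Median log2 change of the expressed genes of each chromosome (horizontal axis) minus the median of all expressed genes (vertical axis, log2), with 1 symbol per comparison with untreated A2780. Chromosome 13 lies at -0.44 on the arrays labelled 24 h and at 0 on those labelled 48 h.

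The comparison at 48 h asks what temsirolimus changed after a second day. The genes with the largest rises were ID2 (2.42 ± 0.09, adjusted p = 2.08e-05) and ID1 (2.24 ± 0.09, adjusted p = 2.08e-05), targets of BMP signalling, followed by HEY1, a transcriptional repressor (1.83 ± 0.08), and NOG, which encodes the BMP antagonist noggin (1.76 ± 0.17). ID3 rose by 1.20 ± 0.09 and the receptor-regulated SMAD9 by 1.31 ± 0.15. Only 33 genes were called, 30 higher and 3 lower, and 12 of them changed at least 2-fold, while 2043 genes had an unadjusted p under 0.05. No gene changed 8-fold.

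The other genes among the 10 largest rises were the glutaredoxin gene GLRX (1.67 ± 0.20), AKAP5 (1.31 ± 0.15), CFAP221 (1.18 ± 0.11) and CRIP2 (1.00 ± 0.12). Further rises outside the rule, chosen after their values were seen, were in ID4 (0.98), SMAD6 (0.91) and SMAD7 (0.96), the latter pair encoding inhibitory SMADs. The 3 lower genes were the pituitary transcription factor gene POU1F1 (-1.37 ± 0.14), SLC44A5 (-0.82 ± 0.12, adjusted p = 0.0468) and B3GALT2 (-0.67 ± 0.10, adjusted p = 0.0489). The last pair lay close to the threshold: with median centring, with a robust prior and without both arrays labelled 24 h only 1 lower gene, POU1F1, was called. With every probe set tested 0 lower genes were called by limma. B3GALT2 measured 4.53 at 48 h, below the lower quartile of every array, so its change can be understated.

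**Figure D3:**
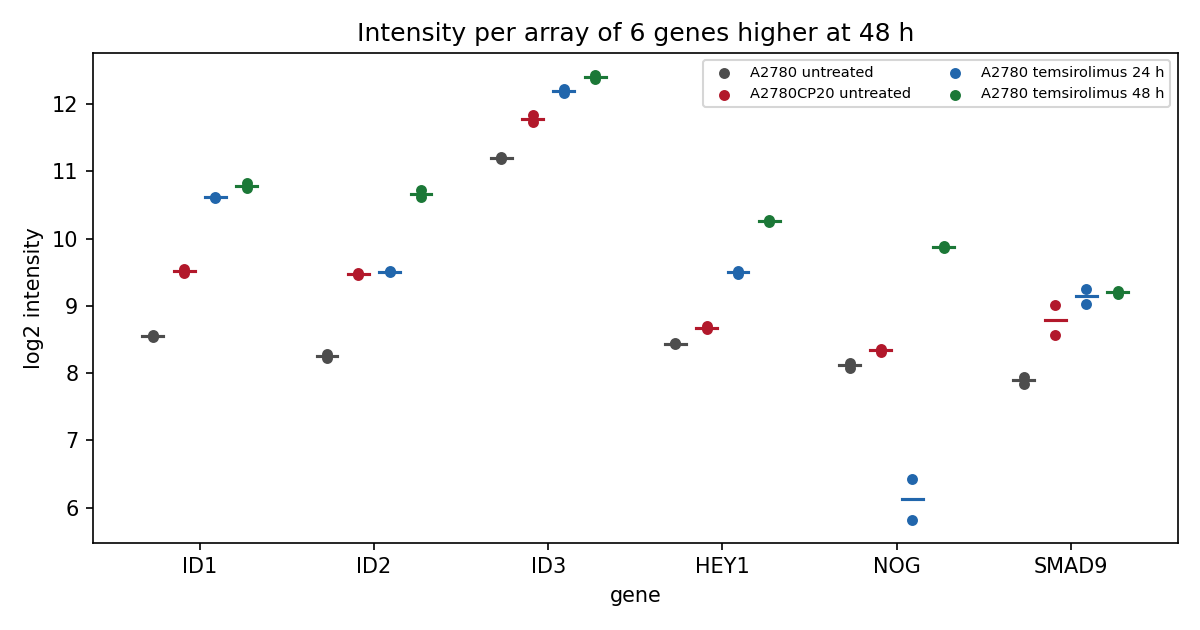
Log2 intensity per array (points) and group mean (bars) of 6 genes that rose at 48 h, with the 4 groups side by side for each gene. For ID1, ID2, ID3, HEY1 and SMAD9 both arrays labelled 48 h lie above both untreated A2780 arrays, and so do both arrays labelled 24 h, whereas NOG is lower at 24 h.

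None of the genes of mTOR signalling, growth control or platinum handling was called at 48 h. MTOR measured 0.06 ± 0.10, RPS6KB1 -0.02 ± 0.11, EIF4EBP1 0.18 ± 0.12, FKBP1A 0.18 ± 0.11, MYC -0.08 ± 0.13, JUN -0.14 ± 0.10, CCND1 0.09 ± 0.09 and CDKN1A -0.21 ± 0.09. ATP7A (0.11 ± 0.18), ATP7B (0.13 ± 0.14), SLC31A1 (-0.03 ± 0.12), ABCC2 (0.04 ± 0.10), GSTP1 (0.20 ± 0.10) and ERCC1 (-0.16 ± 0.10) did not pass either.

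Small shifts were called in 2 of 32 lists at 48 h. Fatty acid synthesis lay higher, with a median of 0.11 over 13 genes and no single member called, over all genes or adjusted over the list alone (camera adjusted p = 0.00226, adjusted p = 0.496 with an estimated correlation). SCD measured 0.33 ± 0.08 and ME1 0.32 ± 0.09. Mitotic genes lay lower, with a median of -0.21 over 29 genes, none called over all genes and 5 lower adjusted over the list alone (camera adjusted p = 5.19e-06, adjusted p = 0.496 with an estimated correlation). DLGAP5 measured -0.34 ± 0.09 and KIF20A -0.48 ± 0.13.

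The count of 33 was 4 without A2780 untreated replicate 1, 5 without A2780 untreated replicate 2, 4 without A2780 temsirolimus 48 h replicate 1 and 6 without A2780 temsirolimus 48 h replicate 2. With an intensity trend in the prior it was 68.

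The arrays labelled 48 h differed from those labelled 24 h about as much as the latter differed from untreated cells. At 48 h versus 24 h, 5702 genes were called, 2804 higher and 2898 lower. DKK1 (7.81 ± 0.14), OSTN (6.82 ± 0.17), SNAI2 (6.60 ± 0.16), VCAN (6.34 ± 0.11) and HAPLN1 (6.09 ± 0.17) were higher at 48 h, and MUC15 (-7.22 ± 0.09), CLDN1 (-7.16 ± 0.14), MID1 (-6.96 ± 0.13), ATP1B1 (-6.46 ± 0.11) and EYA4 (-5.85 ± 0.15) were lower. DKK1, OSTN, MUC15, MID1 and EYA4 again lay below 5.03 in the dimmer group, so their changes can be understated and their order is not certain. All 77 genes at least 8-fold higher and all 93 at least 8-fold lower on the arrays labelled 24 h lay within 2-fold of untreated A2780 at 48 h. Of 32 lists, 10 were shifted, and 0 of these were called with an estimated correlation. Mesenchymal genes had 16 higher and 4 lower of 26 (16 and 5 adjusted over the list alone, camera adjusted p = 9.51e-05, adjusted p = 0.123 with an estimated correlation). The count of 5702 was 3768 without A2780 temsirolimus 24 h replicate 1 and 3715 without A2780 temsirolimus 48 h replicate 2.

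Calls were shared between the comparisons with untreated A2780, which use the same 2 control arrays. Of the genes lower in A2780CP20, 1017 were also lower on the arrays labelled 24 h (338 by independent lists, 997 by simulated lists of the same size), including TXNIP, RPL22 and LUM, and 394 were higher in both (175 by independent lists, 613 by simulated lists). At 48 h, 13 of the 30 higher genes were also higher in A2780CP20 (1.91 by independent lists, 20.2 by simulated lists), among them ID1, ID2, ID3, SMAD6 and SMAD9, and the 3 lower genes were lower in both (0.361 by independent lists, 2.42 by simulated lists). With the arrays labelled 24 h, 14 of the 30 were shared (4.46 by independent lists, 23.8 by simulated lists), including ID1, ID2, ID3, ID4 and HEY1, while NOG and 7 others were lower there. The simulated lists come from unchanged groups that share the control arrays, so they hold only error. In those groups no gene was called in the same direction in 2 comparisons (0 shared calls by limma). Lists of called genes differ from lists of error alone, so the overlap of simulated lists is no expectation for the observed overlap.

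Across genes, the log2 changes of A2780CP20 and 24 h correlated at r = 0.288 (Spearman 0.321) with a covariance of 0.0594, where unchanged groups with shared controls gave r = 0.499 and a covariance of 0.0107. For A2780CP20 and 48 h r was 0.148 (Spearman 0.139) with a covariance of 0.00854, and for 24 h and 48 h it was 0.102 (Spearman 0.178) with a covariance of 0.0121. Leaving out 1 array moved the r of 0.148 to between 0.027 and 0.262 and that of 0.102 to between 0.074 and 0.163. Only the first covariance lay well above the simulated value, by 0.0487. With 1 separate control array for each comparison, r was 0.258 and 0.217 for A2780CP20 and 24 h, 0.115 and -0.083 for A2780CP20 and 48 h, and 0.06 and 0.002 for 24 h and 48 h. Part of the shared calls can come from the shared arrays.

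Markers of other cell types were included as a check. The lists of blood, endothelial, keratinocyte, and hepatocyte and gut markers were not called in any of the 4 comparisons. At 24 h they gave camera adjusted p of 0.996 for blood cells, 0.910 for endothelial cells, 0.667 for keratinocytes and 0.996 for hepatocytes and gut. Single members were called there: 1 higher and 1 lower of 14 blood markers, 1 higher of 7 keratinocyte markers and 1 higher of 10 hepatocyte and gut markers. The lists hold markers of other tissues, so they could not tell A2780 from a subline or another ovarian line.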

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

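Of the tests in this part, those on chromosomes, on genes called at 48 h under exchanged labels, on a graded state, on mixed cells and on the trend shared by the A2780CP20 arrays were chosen only after the results were seen, as was the reading of the normalization, chromosome, window, BMP and left-out-array tests beside other values.

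The arrays labelled 48 h and 24 h differed, which the contrast between them in the limma fit tested as labelled, not as a drug effect over time. It called 5702 genes (30.96% of all tested) and 10 lists, and 68 of the 82 genes named for temsirolimus. Many of the 82 were named for large changes on these same arrays. A high share of calls and opposite signs were therefore likely beforehand and are no separate evidence. Genes higher on the arrays labelled 24 h than in untreated A2780 were lower on those labelled 48 h than on those labelled 24 h, with 48 h minus 24 h log2 differences of -7.22 for MUC15, -7.16 for CLDN1, -6.96 for MID1, -6.46 for ATP1B1, -5.85 for EYA4, -5.78 for ANKRD1, -5.76 for P3H2, -5.67 for VGLL3, -5.64 for ISL1, -5.59 for CLDN16, -3.53 for ABCB1, -3.25 for KRT18, -3.01 for ALDH1A1, -2.59 for SLC7A11, -2.23 for JUN, -2.22 for EPCAM, -1.32 for ZMAT3, -1.15 for RRP9, -1.02 for LYAR, -0.95 for DDIT3, -0.94 for PLK1, -0.92 for RRP12, -0.83 for KIF2C, -0.77 for RRM2, -0.71 for MCM10 and -0.64 for TRIB3. Genes lower on the arrays labelled 24 h were higher on those labelled 48 h, by 7.81 for DKK1, 6.82 for OSTN, 6.60 for SNAI2, 6.34 for VCAN, 6.09 for HAPLN1, 6.03 for CYP1B1, 5.94 for GPRIN3, 5.60 for LUM, 5.56 for CBLN2, 5.53 for NDST4, 5.39 for COL1A2, 3.55 for LIN28A, 3.30 for DCN, 2.06 for CDK6, 1.92 for TP53INP1, 1.79 for TP53I3, 1.65 for CCNG2, 1.46 for RPL22, 1.34 for MYC, 1.34 for ATP7B, 1.23 for TXNIP, 1.20 for CDKN1B, 0.89 for CCND1, 0.80 for CENPF, 0.77 for RPL13, 0.75 for SESN2, 0.71 for ATP7A and 0.29 for CDKN1A.

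Of the genes named at 48 h, the difference was 3.76 for NOG, 1.57 for SLC44A5, 1.16 for ID2, 1.13 for SMAD7, 1.11 for CFAP221, 0.86 for AKAP5, 0.81 for SMAD6, 0.77 for HEY1, 0.58 for SCD, 0.42 for B3GALT2, -0.72 for DLGAP5, -0.80 for KIF20A, -1.37 for ME1 and -3.78 for POU1F1. Lists that differed had median 48 h minus 24 h log2 differences of 0.48 for mesenchymal genes, 0.41 for p53 targets, 0.40 for fatty acid synthesis, 0.21 for mTOR and PI3K-AKT components, 0.20 for cytosolic ribosomal proteins, 0.20 for pluripotency genes, -0.23 for DNA replication, -0.31 for ribosome biogenesis, -0.37 for ATF4 targets and -0.58 for mitotic genes. With an estimated correlation none of the 10 was called. DKK1, OSTN, GPRIN3, NDST4, MUC15, MID1, EYA4, ABCB1 and B3GALT2 lay below 5.03 in the dimmer group, so their differences can be understated.

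The arrays labelled 24 h stood apart from all others, and the 170 genes changed at least 8-fold there lay within 2-fold of untreated A2780 at 48 h. Centring each array on its median (5485 genes still called) was not a test that could fail, since array medians were already near equal. Quantile normalization did move other calls, keeping 3098 of the 3388 for A2780CP20. At 24 h it gave 5576 called genes and kept 5286 of the 5551. However, the quartiles of the arrays were also close before it (lower 5.03 to 5.13, upper 8.62 to 8.75). Quantile normalization thus had little to remove, and these counts do not decide whether differences between arrays gave the 24 h calls. The normalization done before deposit was not tested. Another copy number of chromosome 13, as in a genetically distinct subline or another cell line, could give its departure of -0.44. The next chromosome departed by 0.13, and the largest of 1000 shuffles was 0.175. Over all chromosomes the departures at 24 h followed the trend within the A2780CP20 arrays at r = 0.346, and without chromosome 13 at r = 0.131. In that trend chromosome 13 itself lay at -0.08. The bound written for a response on an unchanged genome as the whole cause was 2 times 0.09, the largest departure between arrays of the same group. At 24 h -0.44 lay beyond this bound and all shuffles, which counts against such a response. A2780CP20 passed the same bound narrowly (0.195, shuffles 0.15) while following the trend within its own arrays, so the response is not excluded. The spread of windows of 50 neighbouring genes over its shuffled mean was 1.84 at 24 h, 1.16 at 48 h and 2.63 for A2780CP20. These ratios met the bounds set beforehand for another line, against a response on an unchanged genome and against an exchange of labels. However, 1.84 decides nothing beside 2.17 between arrays of the same group. The ratio of 2.63 may come from the chromosome trend that also separates the 2 A2780CP20 arrays (r = 0.959). An exchange of labels between A2780CP20 and 24 h stays open. Of the 33 genes called at 48 h, 16 were called in the same direction on the arrays labelled A2780CP20 (1 opposite, 26 of the same sign, median 0.375 in the 48 h direction). On those arrays 18.4% of all genes were called. As many of the 33 were called in the same direction on the arrays labelled 24 h (9 opposite, 21 of the same sign, median 0.16). There 30.1% of all genes were called. The bound written for this test counted the tie against an exchange, although the opposite calls and the medians leaned the other way. Errors of the shared control arrays enter both counts, so the counts do not decide it.

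Changes on the A2780CP20 arrays ran partly along the difference between those 2 arrays. Cells of the kind on the arrays labelled 24 h, mixed in, are argued against by the 77 genes at least 8-fold higher there, whose median change in A2780CP20 was -0.015 with none called higher, although the 93 genes at least 8-fold lower there had a median of -0.53. A trend that also separates the 2 A2780CP20 arrays, such as base composition or RNA quality, may contribute, since over chromosomes the change and the difference between the arrays correlated at r = 0.959. Across genes that correlation was 0.296 (Spearman 0.306), just under the bound of 0.3 set on r for a graded state, against at most 0.035 in simulation. The simulation gave both arrays the same error, so a larger error on replicate 1 alone could also give a positive r. Of the changed genes, 64.6% had the larger change on replicate 1. A graded state cannot be told apart from such an error or from a difference between the lines. No genome sequence was used here, so base composition was not tested, and a biological difference between the lines remains open.

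ID and SMAD genes rose at 48 h. The log2 changes of ID1, ID2 and ID3 kept at least 0.975 of their size whichever of the 4 arrays was left out, so their rise was not on 1 array alone. These genes were called for a small spread between arrays beside their change. That result was therefore likely beforehand and is no separate test of a single array as the source. The bound set beforehand looked at calls instead and was met, with 3 calls lost, each of ID3 (adjusted p 0.0544 to 0.071), and ID4, SMAD6, SMAD7, SMAD9 and NOG, outside that test, lost their calls in all 4 fits (adjusted p 0.0814 to 0.205), with SMAD6 keeping as little as 0.896 of its change. For activation of BMP signalling, 18 BMP-responsive genes not called at 48 h had a median change of 0.012, at the 89.1 percentile of random lists matched on expression (83 to 92.4 leaving out 1 gene), below the bound of 95 set beforehand. That bound was poorly chosen, since the list leaves out the 9 genes that were called and its members lie on both sides of 0 (10 of 18 higher), so BMP signalling cannot be told apart from a change in these few genes by other means.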

How the results depend on the processing

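Each fit with a left-out array leaves 1 array in a group, which is assumed to vary like the others, and fewer arrays leave less power. Where no cause is named, the cause was not tested. The number of arrays limits the precision, signal over background was not measured, and a robust prior was not applied to lists. For A2780CP20 versus A2780, 1022 genes were called with only the 2 groups compared, and 974 to 5543 genes and 1 to 4 lists with an array left out. For 24 h, 3621 to 3919 genes were called with an array left out, for 48 h 4 to 6, and for 48 h versus 24 h 3715 to 3838. A prior with an intensity trend gave 68 genes at 48 h, 5 lists for A2780CP20 and 6 at 48 h. At 48 h, quantile normalization and leaving out the dimmest genes each gave 4 lists. With an estimated correlation 0 lists were called in each of the 4 comparisons. Fry, which asks another question, called 15, 18, 0 and 19 lists. For 48 h versus 24 h, leaving out the dimmest genes ended the calls of fatty acid synthesis and of mTOR components (adjusted p = 0.0584 each), and leaving out 24 h replicate 2 that of pluripotency genes (0.0675). Without both arrays labelled 24 h, 2533 genes were called for A2780CP20 and 25 at 48 h. The labels do not say that replicate numbers pair the arrays. The r of same-numbered deviations was 0.117 to 0.181 among untreated A2780, A2780CP20 and 48 h and 0.002 to 0.039 with 24 h, and with a replicate block 3555, 5642, 35 and 5885 genes were called. All other settings kept the counts of genes within 1.5 times.

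Of the genes taken by the naming rule, a replicate block ended the calls of 3 of 118 for A2780CP20 and 2 of 27 at 48 h. These totals and those below hold the called genes and the genes always included, called or not. Shares of calls lost are therefore larger than the totals show. At 48 h no gene of the always included set was called, so every lost call there was among the 10 higher and 3 lower genes. It ended 0 of 140 at 24 h and 0 of 132 for 48 h versus 24 h. A fit of only the 2 groups compared ended the calls of 47 of 118 for A2780CP20. Leaving out an array ended 8 to 46 of these, 9 to 11 of 140 at 24 h, 8 to 10 of 27 at 48 h and 8 to 10 of 132 for 48 h versus 24 h. Only genes that were never called changed sign. In A2780CP20 ABCC2 was at -0.025 with quantile normalization. With an array left out, ABCC2 ranged from -0.08 to 0.11 (-0.005 without A2780CP20 replicate 1), MTOR from -0.11 to 0.14 (-0.015 without A2780 replicate 1), JUN from -0.12 to 0.07, CDKN1A from -0.02 to 0.07 and GSTP1 from -0.04 to 0.06 (-0.02 without A2780 replicate 1). At 24 h SLC31A1 ranged from -0.03 to 0.26, ABCC2 from -0.11 to 0.08 and ERCC1 from -0.155 to 0.015. At 48 h median centring gave 0.025 for RPS6KB1 and 0.015 for SLC31A1, and with an array left out RPS6KB1 ranged from -0.085 to 0.055, SLC31A1 from -0.17 to 0.12 and ABCC2 from -0.055 to 0.135. For 48 h versus 24 h EIF4EBP1 was at 0.03 with median centring and ranged from -0.085 to 0.075 with an array left out, and FKBP1A from -0.03 to 0.06. The correlation of log2 changes with an array left out ranged from 0.234 to 0.319 for A2780CP20 and 24 h, from 0.027 to 0.262 for A2780CP20 and 48 h, and from 0.074 to 0.163 for 24 h and 48 h.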

Other observations

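Some lists without a camera call held called genes in A2780CP20, where 18.4% of all genes tested were called. Of 15 G1 cyclins and CDK inhibitors, 3 fell and 1 rose (4 and 4 adjusted over the list alone, camera adjusted p = 0.922, adjusted p = 0.961 with an estimated correlation). The CDK inhibitor gene CDKN1B measured -0.79 ± 0.09, the unconventional cyclin gene CCNG2 -0.75 ± 0.11 and the CDK inhibitor gene CDKN2B 0.45 ± 0.13. Of 20 targets of p53, 6 fell and 1 rose (the same counts adjusted over the list alone, camera adjusted p = 0.277, adjusted p = 0.506 with an estimated correlation), with TP53INP1 at -0.91 ± 0.19 and TIGAR at -0.51 ± 0.10. The mitophagy receptor gene BNIP3L was at -1.22 ± 0.13 among 16 hypoxia-responsive genes, of which 4 fell and 1 rose (4 and 2 adjusted over the list alone, camera adjusted p = 0.356, adjusted p = 0.604 with an estimated correlation). The lysosomal membrane protein gene LAMP2 was at -1.02 ± 0.10, and 4 of 24 lysosome and autophagy genes fell (3 adjusted over the list alone, camera adjusted p = 0.106, adjusted p = 0.427 with an estimated correlation).

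Of 13 fatty acid synthesis genes, 3 rose and 1 fell in A2780CP20 (the same counts adjusted over the list alone, camera adjusted p = 0.627, adjusted p = 0.873 with an estimated correlation), whereas 8 of 19 cholesterol genes fell. SREBF1, a transcription factor of lipid synthesis, rose by 0.77 ± 0.10, and FASN, which encodes fatty acid synthase, by 0.63 ± 0.11, while ELOVL6 was at -0.57 ± 0.11. Hexokinase 2 (HK2) rose by 0.58 ± 0.10 and PFKP by 0.44 ± 0.09. Of 19 glycolysis genes, 4 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.106, adjusted p = 0.427 with an estimated correlation).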
